A study of Pimephales promelas with 47 samples.

How the data were processed

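RNA from fathead minnow (Pimephales promelas), a small freshwater fish used in toxicology, was measured on 47 single-colour (Cy3) oligonucleotide arrays. The fish had been kept for 7 weeks in water with phenanthrene, a polycyclic aromatic hydrocarbon, at 201.8 µg per L, or in water with the solvent. There were 8 arrays for each combination of sex and exposure in the hypothalamus, and 7 control and 8 phenanthrene arrays of female liver. Groups were taken from the sample labels, and each scanner file was assigned to the sample it is recorded under. The labels do not state that the arrays of a group come from separate fish. The title numbers differ within each group, so p-values measure the spread between these samples.

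The processed intensity of each spot was deposited by the authors in 1 scanner file per array. Per the file headers, it was made with Agilent Feature Extraction 10.7.1.1 and a single-colour protocol, with background subtraction and detrending within the array, small values replaced by a positive surrogate, and no adjustment between arrays. Each array holds 15744 spots, of which 15208 are probes, each spotted once. The deposited value table holds the authors' processed values on a log2 scale. Its normalization and centring are not given in the sources used here. Column medians run from 7.33 to 7.60 in the female hypothalamus, from 7.10 to 7.18 in the male hypothalamus and from 6.43 to 6.60 in the liver.

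The log2 of the processed intensity was taken and the 75th percentile of each array was subtracted, so levels are log2 units relative to that percentile. A probe was tested if it was well above background on at least 50% of the arrays of a group in the fit. Outlier flags, on 0.300% of the probe values, removed nothing because no probe has a second spot. Group means were fitted with limma 3.58.1 in R 4.3.3 (lmFit and eBayes), with Benjamini-Hochberg adjustment and a threshold of 0.05. The 32 hypothalamus arrays shared a fit, the 15 liver arrays had their own, and the 31 female arrays were fitted together for the difference between tissues. Intervals cover 95%. The number of arrays limits the precision. These comparisons and most alternatives were fixed before the data were examined. The alternatives were another background correction, quantile and median scaling, other probe filters, the authors' processed values (fitted on 1 sex or tissue under the sample links of the table), array weights, left-out arrays, slide and scan date as blocks, and fits of 1 sex alone. The normexp correction (offset 50) used median foreground intensity, because the mean was not among the columns read.

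The files do not pair the probes with genes. The sequence names of 0 of the 15208 probes were found in the gene table of the fPimPro1.hap1.1 assembly. The gene lists and the rule for named genes fixed beforehand, which needed gene names, were therefore not applied. Probes are given by their identifiers instead. Where a comparison had calls, these are up to 2 probes with the largest difference in each direction, and otherwise the probe with the smallest p. That choice, and a pair of probe sets defined by tissue, were made after the values were seen.

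Each model was tested on simulated data with each probe's mean and each group's own spread, with 200 probes changed. The noise was drawn independently for each probe and array. Deviations that the probes of an array share are thus absent, and the rates below may differ from those in the real data. In the female hypothalamus comparison, on 13542 probes, 34% of the 2-fold and 66% of the 4-fold changes were recovered, but 130 of 209 calls were false, as the shared fit takes too small a spread for the more variable females. With the female arrays alone, on 13293 probes, 3 of 49 calls were false and 56% of 4-fold changes were recovered. For the male comparison in the shared fit, on 13542 probes, recovery was 20% at 2-fold and 70% at 4-fold, with 1 of 78 calls false. With the male arrays alone, on 12561 probes, it was 58% and 98%, with 14 of 151 calls false. In the liver, on 10209 probes, it was 20% and 68%. For the difference between tissues, on 13707 probes, only 16% of 4-fold changes were recovered. For the difference between sexes in exposure effect, on 13542 probes, it was 56%.

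The arrays lie on 10 slides scanned on 4 dates. Each slide holds 1 sex and tissue. Female hypothalamus arrays were scanned on 2 dates, and male hypothalamus and liver arrays on 1 date each. No files of any group held duplicate arrays; the highest correlation between arrays of a group was 0.971.

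Title numbers recur between female liver and female hypothalamus arrays for 8 numbers, always with the same exposure. Over the 200 most variable probes, after quantile normalization within each tissue, the correlation of deviations from the group means between the arrays of a number ran from 0.21 to 0.42. Over all 6840 probes well above background on over 80% of the arrays of both tissues it ran from 0.016 to 0.28. It was under 0.1 for 2 of the 8 numbers, so over all probes the pairing is weak. The labels do not state that a number is a fish. The numbers were treated as pairing samples in the check of the sample links and in the alternatives with a replicate block.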

Results

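The study asked how waterborne phenanthrene affects the transcriptome of the hypothalamus in a teleost fish, with female liver as a second tissue. Control and exposed fathead minnows were compared within the female hypothalamus, the male hypothalamus and the female liver. Between 69.4% and 86.3% of probes were well above background on each male hypothalamus array, between 54.0% and 95.2% on the female hypothalamus arrays and between 48.0% and 77.4% on the liver arrays. In the female hypothalamus this share was 83.8 ± 5.1% in controls and 74.3 ± 12.8% in exposed fish (mean ± SD, n = 8 each). The lowest shares were on exposed arrays 10 (54.0%) and 41 (55.5%). The 16 male hypothalamus arrays resembled each other closely. The mean correlation of each with the rest of its group was 0.949 or more. Among the female hypothalamus arrays, 4 stood apart, namely controls 14 and 56 and phenanthrene arrays 26 and 29. The SD of their log2 signal over probes was at most 1.92, against 2.62 to 3.33 on the other 28 hypothalamus arrays. The lowest signal on these 4 arrays was 11.1 to 126 intensity units, against at most 8.44 on the others. They are called low-spread arrays here.

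**Figure D1:**
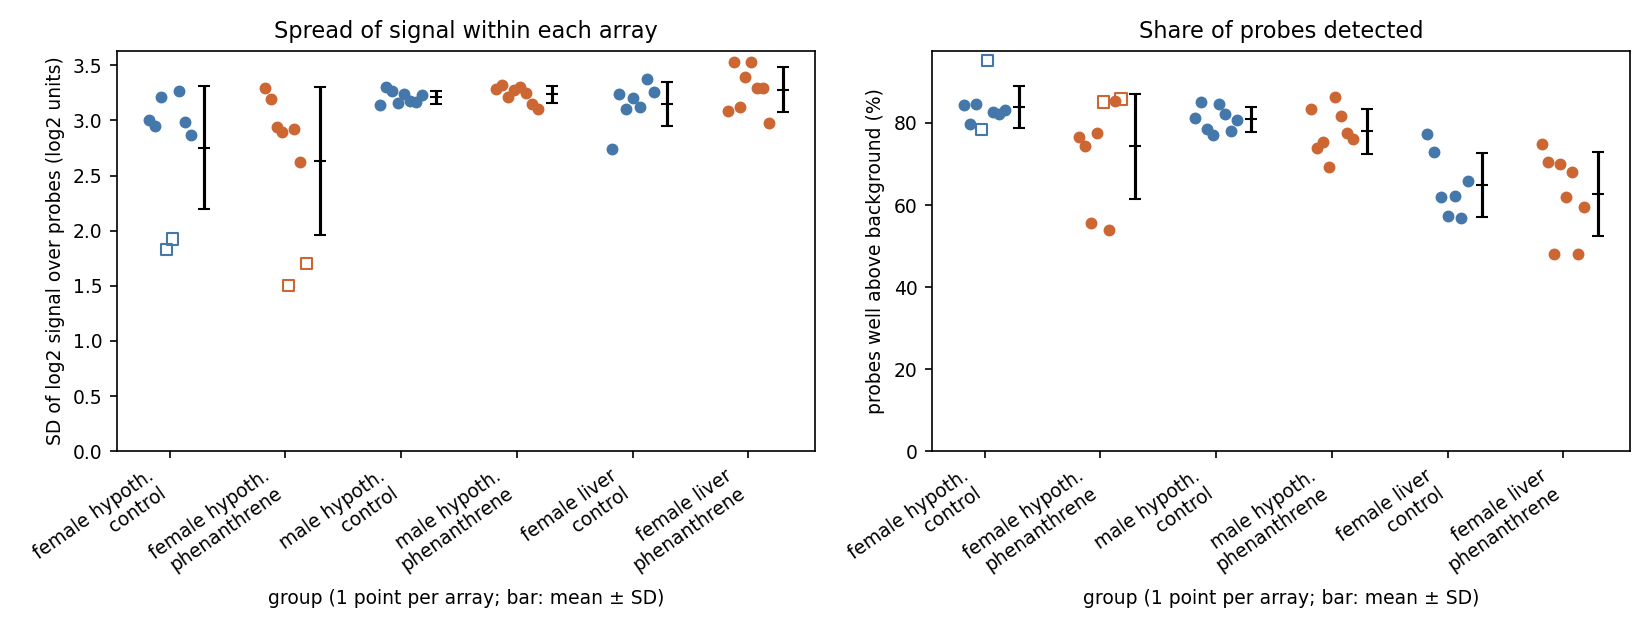
SD of log2 signal over probes (left, log2 units) and percent of probes well above background (right) for each array, by group; points are arrays, open squares the 4 low-spread arrays, bars the mean ± SD. The low-spread arrays lie at 1.92 or less in the left panel, below all other arrays.

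The authors' value table and the scanner files did not link the same arrays to the same samples. In the female hypothalamus, 11 of 16 columns of the table matched the scanner file of another sample, and for 6 of these the exposure differed. The rows of the male and liver columns did not follow their probe identifiers, with Spearman correlations between -0.01 and 0.014. Matching rows through the liver arrays alone, under their own links, placed 11435 of 15208 rows, against at most 2 with 20 shuffles of those links. With each of the 15 liver columns left out of the matching in turn, the left-out column matched its own scanner file, at 0.893 to 0.998, and other files at 0.337 or below. On the rows placed, each of the 16 male columns matched the file of a male array on the other slide, at 0.983 or above. All 16 of those files are recorded under the opposite exposure. The correlation of a male column with its own file was at most -0.02.

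The links were checked in females through the 8 title numbers that have both tissues. This check was chosen after the conflict was seen. Over the 200 probes that varied most in both, the liver and hypothalamus arrays of a number correlated in their deviations from the tissue median, with a mean Spearman rho of 0.28. The exact permutation p was 2.5e-05 (1-sided, 40320 pairings), the smallest these pairings can give. For 7 of the 8 numbers the array under its scanner link ranked first among all 16 hypothalamus arrays. For the 6 numbers in conflict, mean rho was 0.29 with the scanner links and -0.01 with the links of the table. The scanner links were used throughout, also for females 14, 26, 29, 37 and 46, which are in conflict and have no liver array to check them. For males no second tissue was measured. Every male fold change below turns its sign if the links of the table are the right ones, so the direction of the male exposure effect is unsettled.

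**Figure D2:**
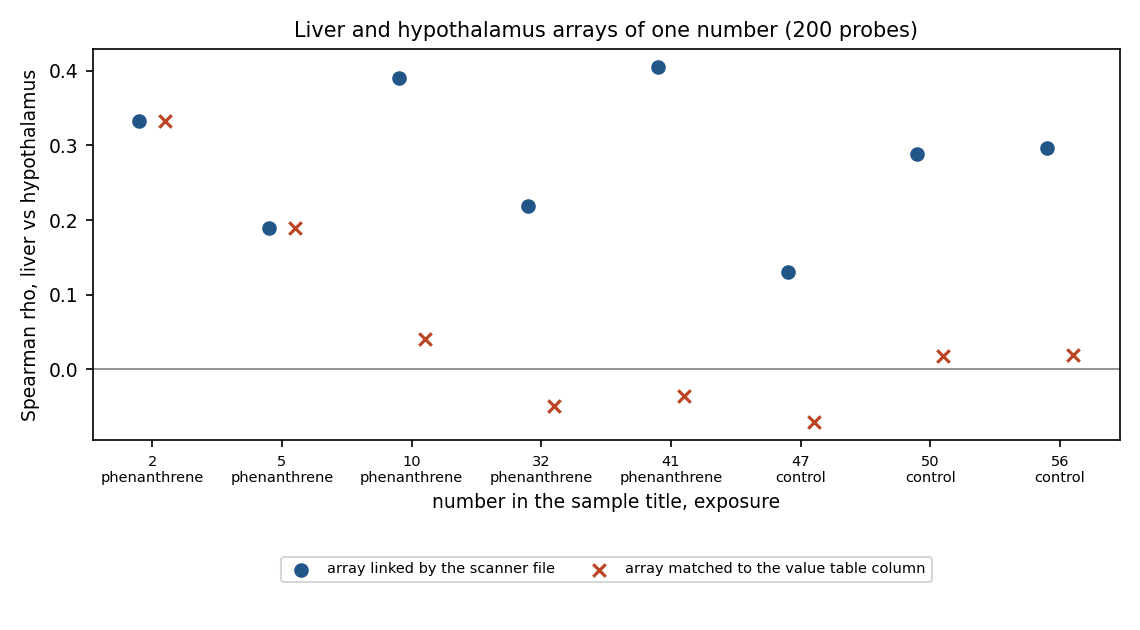
Spearman rho between the liver array and the hypothalamus array of each title number over 200 probes; circles use the array linked by the scanner file, crosses the array whose values match the value table column. For the 6 numbers whose links differ, circles average 0.29 and crosses -0.01.

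In the female hypothalamus, 1 probe of 13542 passed the threshold. UF_Ppr_AM_120462 was lower in exposed females, at -1.51 ± 1.01 (SD, n = 8) against 0.37 ± 0.52 (SD, n = 8) in controls. The log2 fold change was -1.88 ± 0.33 (SE), limma adjusted p = 0.045, and all 8 exposed arrays lay below the control mean. At an unadjusted p under 0.05 there were 859 probes, 213 higher and 646 lower with exposure, where 677 are the number under uniform p-values. The median 95% interval of a probe reached 0.75 log2 units to either side. It comes from the spread shared with the males, which is too small for the more variable females. The interval, the SE and the adjusted p of this fit therefore make the female comparison look more precise than it is. The call was lost in the fit of female arrays alone, where 0 probes passed and 337 had an unadjusted p under 0.05, with the fold change still -1.88. It was also lost with slide as a fixed block (-1.32), with each array centred on its median (-1.94, adjusted p = 0.15), without a filter (-1.88, adjusted p = 0.057) and in the authors' values. The probe passed in 10 of 19 alternatives, among them quantile scaling (limma adjusted p = 0.0021). Of the alternatives fixed beforehand, array weights gave 253 calls, 34 higher and 219 lower. Leaving out the least correlated array of each group gave 53. Without the 4 low-spread arrays, an alternative added after seeing the data, 222 probes passed, 52 higher and 170 lower. Only 3 passed when the females were fitted alone, although the fold changes are then the same and all 222 had an unadjusted p under 0.05. In simulated data without these arrays, with noise independent between probes, 47 of 167 calls of the shared fit were false. Within scan date 1 (3 controls, 2 exposed) 2 probes passed and within scan date 2 (5 controls, 6 exposed) 0 passed. Fold changes of these dates correlated at 0.15 across probes, which are not independent replicates. Within slide 5 (2 controls, 4 exposed) 0 probes passed and within slide 6 (3 controls, 2 exposed) 1 passed, and their fold changes correlated at -0.84. Both controls of slide 5 (14 and 56), 1 of its exposed arrays (29) and 1 of the 2 exposed arrays of slide 6 (26) are low-spread arrays. The other slides held 1 exposure each.

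In the male hypothalamus 0 of 13542 probes passed with limma. An unadjusted p under 0.05 was found for 210, where 677 are the number under uniform p-values. The shared fit takes too large a spread for the less variable males, so this absence of calls is weak evidence. Fitted alone, the male arrays again gave 0 calls and 1128 of 12561 probes with an unadjusted p under 0.05. The probe with the smallest p was UF_Ppr_AF_115417. It was at 0.92 ± 0.42 (SD, n = 8) in exposed and 1.83 ± 0.31 (SD, n = 8) in control males by the scanner links, a log2 fold change of -0.90 ± 0.20 (SE) with a limma adjusted p of 0.86. All 8 exposed arrays lay below the control mean. With the links of the value table this difference is 0.90. Both slides held 4 arrays of each exposure. Within slide 7, 0 probes passed and within slide 8, 4 passed. The fold changes of these slides correlated at 0.086 across probes.

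The difference in exposure effect between males and females was tested directly. Of 13542 probes 0 passed with limma, and 654 had an unadjusted p under 0.05. The median 95% interval of this difference reached 1.06 log2 units to either side. Log2 fold changes of the 2 sexes, which share no array, correlated at -0.18 across probes (Pearson) and -0.23 (Spearman). Among 100 labellings of the arrays within each sex, the real one included, 14 gave a Pearson value as far from 0. With the male links of the value table the correlation is 0.18 and 1 probe passed the test of the difference.

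In the female liver 0 of 10209 probes passed with limma. At an unadjusted p under 0.05 there were 619, of which 533 were lower with exposure. The median log2 fold change of all probes was -0.15, and with each array centred on its median it was 0.16. Such centring shifts all fold changes by the same amount, so the balance of directions over all probes depends on the scaling. Directions of the probes at an unadjusted p under 0.05 were not counted under that scaling. The smallest p belonged to UF_Ppr_AF_115303, at -4.47 ± 0.81 (SD, n = 8) in exposed and -2.53 ± 0.70 (SD, n = 7) in control livers. Its log2 fold change was -1.94 ± 0.38 (SE), limma adjusted p = 0.29, and it was well above background on 3 of 8 exposed and 6 of 7 control arrays. With normexp background correction the value was -0.93, so its size depends on the treatment of background. Within slide 9 (3 controls, 4 exposed) 1 probe passed and within slide 10 (4 of each) 0 passed. Fold changes of these slides correlated at 0.022 across probes. The difference in exposure effect between liver and female hypothalamus was past the threshold for 0 of 13707 probes with limma, with 299 at an unadjusted p under 0.05.

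Control males and control females differed in the hypothalamus at 17 of 13542 probes, 15 higher and 2 lower in males. At an unadjusted p under 0.05 the balance was the opposite, with 671 higher and 1885 lower of 2556 probes. With each array centred on its median, 499 probes passed, 106 higher and 393 lower, so the balance of directions depends on threshold and scaling. UF_Ppr_AF_117623 was at 2.10 ± 0.24 (SD, n = 8) in males and -0.18 ± 0.77 (SD, n = 8) in females, a log2 difference of 2.28 ± 0.33 (SE) with a limma adjusted p of 0.00070. UF_Ppr_AF_103802 was higher by 2.29 ± 0.42 (SE), at 5.07 ± 0.54 in males and 2.78 ± 0.93 in females (SD, n = 8 each, limma adjusted p = 0.017). For both probes all 8 male arrays lay above the female mean. The 2 probes lower in males were well above background on 0 of 8 male arrays. UF_Ppr_AF_106707 was at least 3.89-fold higher in females (limma adjusted p = 0.036), well above background on 7 of 8 female arrays. UF_Ppr_AF_104108 was at least 2.93-fold higher in females (limma adjusted p = 0.036), well above background on 5 of 8. These bounds set the female mean against the lowest signal well above background on each male array, or the probe's own value where higher. On the 2 low-spread control arrays both probes read higher than on the other 6 female arrays. Without those arrays the bounds fell to 2.18-fold for UF_Ppr_AF_106707 and 1.61-fold for UF_Ppr_AF_104108 (limma adjusted p = 0.0068 and 0.00069). With normexp background correction neither passed (limma adjusted p = 0.93 for both). The male minus female log2 differences were then -0.69 for UF_Ppr_AF_106707 and -0.44 for UF_Ppr_AF_104108, smaller in size than these bounds. The bounds therefore hold only for the processed intensity. The sexes were on separate slides and scan dates. With scan date as a random block 0 probes passed, although all 17 kept their direction. Their median difference in size was 1.70 without and 1.66 log2 units with the block, while the median SE went from 0.27 to 0.40. In exposed fish, which share no array with the controls, the same 17 probes all differed in the same direction, in a fit that shares its spread with the controls, and 13 passed the threshold there among 1073 calls. Exposed arrays of each sex shared scan dates with the controls of that sex, so this agreement cannot tell sex from batch. Under the male links of the authors' values, 4 of the 17 passed and no others did.

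**Figure D3:**
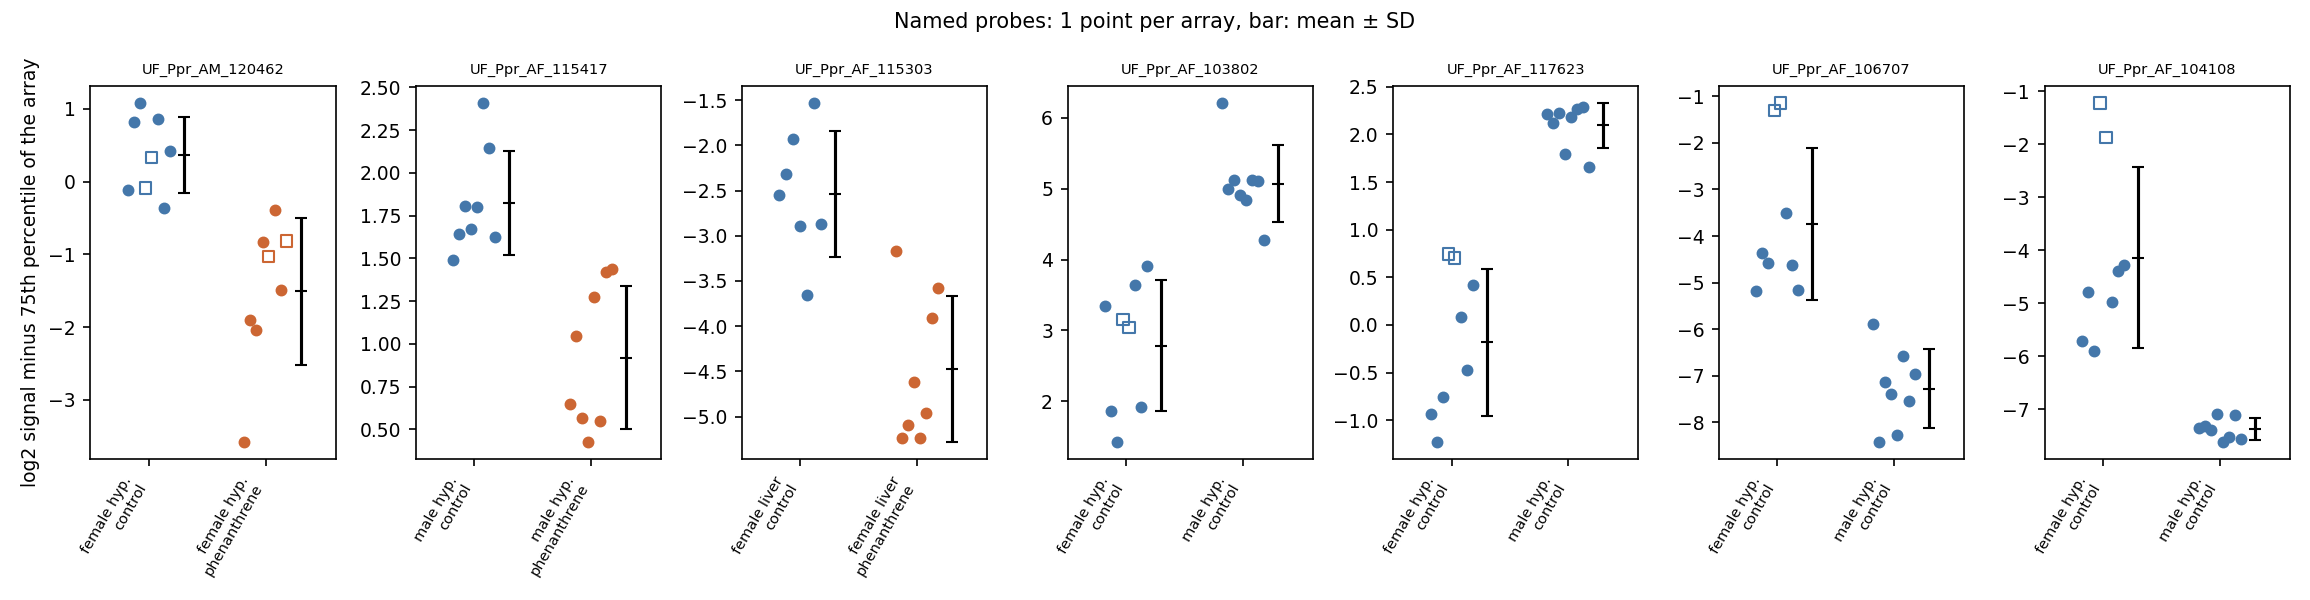
Level of each named probe (log2 signal minus the 75th percentile of the array) in its pair of groups; points are arrays, open squares low-spread arrays, bars the mean ± SD. From left, the first 3 probes compare exposure in female hypothalamus, male hypothalamus and liver, and the last 4 compare control females with control males.

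Liver and hypothalamus differed widely in females. Averaged over exposure, 3868 of 13707 probes were higher in liver and 4855 higher in hypothalamus. UF_Ppr_AF_102268 was at 7.69 ± 0.54 (SD, n = 15) in liver and well above background on 0 of 16 hypothalamus arrays, at least 4943-fold higher in liver. UF_Ppr_AF_105294 was at 8.67 ± 0.78 (SD, n = 16) in hypothalamus, and well above background on 1 of 15 liver arrays, at least 7329-fold higher in hypothalamus by the same kind of bound (limma adjusted p = 7.4e-27). Each slide and scan date held 1 tissue. For UF_Ppr_AF_105294 the SD over hypothalamus arrays on 6 slides and 2 dates was 0.78 log2 units, far below the difference. For UF_Ppr_AF_102268 it was 1.35, but there the probe was not well above background. Neither SD measures a shift between hypothalamus and liver slides, so by design tissue and batch cannot be told apart.

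Probes at least 4-fold higher in a tissue formed a pair of sets, liver-high (1460 probes) and hypothalamus-high (2387 probes). The sets were defined on the same female arrays, averaged over exposure. Of the 1240 liver-high probes tested in the female hypothalamus, 0 passed singly, and 70.8% had a lower mean in exposed fish. Their median log2 fold change was -0.21, against -0.06 over all probes. With a preset correlation of 0.01, camera gave an adjusted p of 0.00024 over 6 tests. The adjusted p was 0.35 with an estimated correlation. Their median was -0.28 and -0.18 within the scan dates, against -0.16 and -0.05 over all probes, and -0.18 and -0.17 within slides 5 and 6, where the medians of all probes were -0.41 and 0.38. Liver-high probes read lower in hypothalamus by definition, and a probe could be tested through 1 group alone. Exposed females had fewer probes above background than control females (means 74.3% and 83.8%). Whether this bears on the direction was not tested, as the sets were not run with normexp or on probes above background on every array. In males the liver-high median was 0.04 by the scanner links, against -0.03 over all probes (adjusted p = 0.0082 with the preset and 0.48 with an estimated correlation), and -0.01 and 0.09 within slides 7 and 8, against -0.08 and 0.01 over all probes. In liver, the 1460 liver-high probes had a median of -0.16 (adjusted p = 0.99 with the preset correlation). The 808 hypothalamus-high probes tested there had a median of -0.06, above the -0.15 of all probes (adjusted p = 0.0082 with the preset and 0.49 with an estimated correlation), and -0.19 and 0.02 within slides 9 and 10, against -0.31 and -0.03 over all probes. With quantile normalization it was 0.16 against -0.02 over all probes (adjusted p = 0.00020 with the preset correlation), so the set lay above all probes under both scalings. The hypothalamus-high set gave an adjusted p of 0.13 in the female hypothalamus, at a median of 0.00, and 0.22 in the male. Without the 4 low-spread arrays its female median was 0.09 against -0.02 over all probes (adjusted p = 0.0021 with the preset and 0.32 with an estimated correlation), and the liver-high median was -0.16 (adjusted p = 0.0021 and 0.32).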

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

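The tests of explanations in this part, and the alternatives without low-spread arrays, were chosen after the results they bear on had been seen. The exception is the fit of control males and females with scan date as a random block, which was fixed beforehand. In 38 sets of values, each 1 quality measure or named probe in 1 group, 6 values lay far from the rest of their group; chance gives about 1 in 20 sets. Control female 56 had 95.2% of hypothalamus probes above background, with the next at 84.6%. Control female 14 had a mean correlation of 0.663 with its hypothalamus group, with the next at 0.805. Control liver 34 had an SD of log2 signal of 2.74, with the next at 3.10, and a mean correlation of 0.882, with the next at 0.913. Control male 20 had a mean correlation of 0.949 with its group, with the next at 0.957. For UF_Ppr_AF_103802, control male 13 read 6.21, with the next at 5.12.

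The value table and the scanner files disagree on which array belongs to which sample in 11 female and 16 male hypothalamus arrays. A wrong scanner link is argued against for the 6 conflicting numbers with a liver array (10, 32, 41, 47, 50 and 56). Their arrays shared deviations with the liver more than all other assignments of the 11 conflicting arrays (exact permutation p = 3.0e-06, the smallest of 332640 assignments). Through the table these numbers shared none (exact permutation p = 0.55), as wrong columns in the table would give. The links of females 14, 26, 29, 37 and 46 are in conflict too, but without a liver array they could not be checked. For the 16 male columns, which all match an array of the opposite exposure, no second tissue decides. Of the 11 female columns in conflict 10 match an array of another slide, as do all 16 male columns, so a like slip in the table is a candidate explanation for males too, untested there.

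Without the 4 low-spread arrays the female hypothalamus gave 222 calls instead of 1, and of 100 splits of the remaining 12 female arrays in the same fit, 3 gave as many, the real one included, and the highest other gave 412. That argues against chance for this count in that fit only, as leaving these arrays out was chosen after the data were seen. With females alone 5 of 100 splits reached the real 1611 probes at an unadjusted p under 0.05, so chance could not be excluded there. Too small a pooled spread stays open. The female SD of the called probes was 1.13 times the pooled SD (median). In simulated data with noise independent between probes, 47 of 167 calls were false. With females alone, where fewer arrays estimate the spread, 3 of the 222 calls were kept. Slide remains open and cannot be told apart from exposure: slide 5 then holds 3 exposed arrays and 0 controls, and slide 6 holds 1 and 3. A fixed slide block therefore sets 1 exposed array (46) against 3 controls, so the 7 calls kept with it decide nothing; with scan date as a block 184 were kept.

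For the control males and females, 1 of 100 splits of the 16 arrays gave 17 calls, the real one, and the highest other gave 0. That argues against chance as the source of the count. It cannot tell sex from batch, as the other splits mixed slides and scan dates that differ between the sexes. The low-spread arrays are argued against as the cause, since all 17 probes were called without them. Scan date cannot be told apart from sex, as each date holds 1 sex, so the block decides nothing: 0 probes passed with it as a random block because the errors grew, not because the differences shrank. UF_Ppr_AF_117623 went from 2.28 ± 0.33 to 2.36 ± 0.45 and UF_Ppr_AF_103802 from 2.29 ± 0.42 to 2.38 ± 0.60 (SE). A biological sex difference stays open and untested.

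In the female hypothalamus 19 of 100 splits gave at least 1 call, so chance could not be excluded. The highest gave 7778, which points to a structure of the arrays other than exposure. For the male hypothalamus, the liver, the difference between sexes and the difference between tissues the real count was 0, so all 100 splits had to give as many, which decides nothing; the highest other gave 0, 35, 3586 and 8. At an unadjusted p under 0.05, chance could not be excluded either: 12 of 100 splits of the male arrays alone reached the real 1128 probes, 21 of the liver arrays the real 619, 35 of the female arrays alone the real 337, 23 the real 654 of the difference between sexes and 59 the real 299 of the difference between tissues.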

How the results depend on the processing

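Alternatives involving the low-spread or dimmest arrays, control arrays alone, the male links of the table or the authors' values under scanner links were chosen after seeing the data. The cause of a change was not tested unless given. Female hypothalamus, against 1 call: normexp 2, quantile scaling 3, median centring 0, no filter 0, probes above background on every array 2, authors' values 0 with females alone under the links of the table and 0 under the scanner links, array weights 253, without the least correlated array of each group 53, slide as a fixed block 0, females alone 0. Without the 4 low-spread arrays it was 222, with scan date as a block 204, with slide as a block 156, and 3 with females alone; that slide block leaves 1 exposed array (46) against 3 controls on slide 6, assumed to vary like the other groups. The 156 are mostly other probes than the 222: that slide block moved the median log2 fold change of all probes from -0.03 to 0.25. Most of its calls were higher with exposure, where most of the 222 were lower, although 204 of the 222 kept their direction. Without the 2 females with the fewest probes above background (10 and 41, both exposed) the number of calls was 0, and without all 6 it was 103. Leaving out 10 and 41 alone moved the median log2 fold change of all probes from -0.06 to 0.08. Slide as a random block and scan date as a fixed block left 1. UF_Ppr_AM_120462 stayed lower throughout (-2.40 to -1.02), with a lowest adjusted p of 0.0021; it passed in 10 of 19 alternatives. The -1.02 is from the authors' values under the links of the table, which join 6 females to the other exposure; under the scanner links the same values gave -1.79 (adjusted p = 0.58).

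Array weights gave 5 calls in males (0 higher) and 183 for the difference between sexes; the male links of the table gave 1 for that difference, turned the correlation between the sexes to 0.18 and UF_Ppr_AF_115417 to 0.90. All other alternatives run for males and that difference, and all run for liver and the difference between tissues, gave 0. Control males against females, 17 calls: normexp 11 (0 lower), quantile scaling 67, median centring 499 (106 higher, 393 lower; the median of all probes moved from -0.08 to 0.29), array weights 2103, without the least correlated arrays 30, scan date as a random block 0, control arrays alone 182, without the 4 low-spread arrays 315, both together 704, and 4 under the male links of the authors' values.

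For the difference between tissues, the replicate block with pairing by title number gave 0 calls as a random block (308 at an unadjusted p under 0.05) and 0 as a fixed block (1004, over the paired arrays only); it changed no call. Scaling moved the median log2 fold change of all probes: with normexp from -0.06 to 0.20 in females, from -0.03 to 0.25 in males and from -0.14 to -0.54 for the difference between tissues, and with median centring to 0.23 for the latter, from -0.15 to 0.16 in liver and from 0.03 to 0.14 for the difference between sexes. Not run: all gene list alternatives, as probes have no gene names; authors' values for comparisons across sexes or tissues, as their rows are ordered differently; scan date as a block in the liver, which has 1 date. Of 90 alternatives for single named probes, 89 kept the direction, of which 68 also kept the side of the threshold. UF_Ppr_AF_115417 passed with array weights alone (adjusted p = 0.025). Signal over background limits dim probes: normexp moved UF_Ppr_AF_106707 to -0.69, UF_Ppr_AF_104108 to -0.44 and UF_Ppr_AF_115303 to -0.93.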

Other observations

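The tests in this part were chosen after the data were seen. Liver and hypothalamus arrays with the same title number deviated together at a set of probes. Of 6840 probes well above background on over 80% of the arrays of both tissues, 74 correlated above 0.9 over the 8 numbers that have both. The median over the 720 pairings within an exposure was 13 and the highest other pairing gave 58 (exact permutation p = 0.0014, the smallest these pairings can give). This count restates, over all probes, the shared deviations by which the sample links were checked, so it is no independent evidence. The labels do not state that a number is a fish, and no explanation was tested.

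The array carries 14498 probes in one name series and 710 in another, marked AM in the identifier, and 709 sequences have a probe of each. Over these sequences the levels of the 2 probes did not correlate (-0.0023), and their median difference was -2.51 log2 units, AM minus the other. An AM value therefore cannot be read as a repeat of the other probe's reading. UF_Ppr_AM_120462, the 1 call for female exposure, is an AM probe. AM probes were over-represented among low p-values for female exposure. With an unadjusted p under 0.05 there were 12.9% of 502 AM probes and 6.09% of the others (Fisher's exact test p = 3.4e-08, probes are not independent), 62 of them lower and 3 higher in exposed females. Between control males and females the shares were 36.7% and 18.2% (Fisher's exact test p = 1.8e-21), with 161 AM probes lower and 23 higher in males. Both comparisons use the same 8 control females, so these excesses are not independent. For exposure in males the shares were 1.39% and 1.56%, and in liver 7.24% and 6.03%. These AM probes were 7 lower and 0 higher in exposed males by the scanner links, and 21 lower and 0 higher in exposed livers. Of all probes at that p, 126 of 210 in males and 533 of 619 in liver were lower. The male fit gave 210 such probes where 677 are the number under uniform p-values, so its shares cannot be set against the female ones. Without the low-spread arrays 50 of the 222 calls were AM probes, 48 of them lower. AM probes were dimmer, well above background on a median of 40.4% of arrays against 87.2% for the others. No explanation for the excess was tested.

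Without the low-spread arrays, female log2 fold changes from scan date 1 (5 arrays) and scan date 2 (7 arrays) correlated at 0.24 across probes.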
